A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

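Poly(A) RNA of 2 baker's yeasts, LS and HS in the labels, was taken after 60 min of fermentation in what the labels call LF medium with 0, 5, 10, 20, 30, 40 or 50% sucrose, and was hybridised to Affymetrix arrays with probe sets of S. cerevisiae and S. pombe. The labels do not say what LS and HS stand for or what LF medium holds. The 14 groups of yeast by sucrose had 2 replicates each, 28 arrays in all, and nothing in the labels says that replicates came from separate cultures or gives a date or batch.

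The deposited values are per the labels a normalized ratio on a linear scale. According to the series design text the authors worked in GeneSpring v7.0, scaling each chip on its genes with positive values, S. pombe left out, and then scaling each gene. A check of the table found a median of 1 (within 0.006) for 97.7% of S. cerevisiae probe sets and 7.45% of S. pombe probe sets, so a value compares arrays within a probe set and carries no level between genes. Values ran from 0.01 (188 values) to 532.3. For 125 S. cerevisiae probe sets the median lay below 1. They are called probe sets of low signal, a name that rests on this median alone, as signal levels were not analysed here. How signal was summarised over the probes of a set is not given in the sources used here.

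Of 10928 probe sets 7244 had 1 gene symbol, 1 had several and 3683 had none. The 5498 S. cerevisiae probe sets with a symbol, for 5449 genes, were tested; 12 outdated symbols were updated. The 1746 S. pombe probe sets were kept as a background. Probe sets with the suffix s_at (103) or x_at (25) can also read related sequences by design of the array, and 47 genes had several probe sets. Unnamed probe sets were not used in the comparisons.

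Log2 values went without further scaling into a cell-means model of the 14 groups in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation without trend, 14 residual degrees of freedom and 5.41 prior degrees of freedom. Tests were 2-sided, with Benjamini-Hochberg adjustment over the 5498 probe sets within each comparison and a call at an adjusted p under 0.05. The 9 main comparisons were 5% against 0%, 40% against 5% and 50% against 5% sucrose in each yeast, HS against LS as the mean over the 7 concentrations, and the HS minus LS difference of the responses to 5% and to 40%. Another 13 gave 10, 20 and 30% against 5% in each yeast and HS against LS at each concentration. Differences are the first named group minus the second. The number of arrays limits the precision.

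Gene groups were 33 lists fixed before the data were examined, tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, with 1 probe set per gene. Members were also called with adjustment over the list alone. Genes named in the text were the 5 largest rises and 5 largest falls among called probe sets with 1 symbol whose groups did not overlap (for HS against LS, with the same sign at all 7 concentrations), up to 4 called members with the largest change in lists with at least 3 calls or a camera adjusted p under 0.05, and a fixed set of 10 genes of glycerol, trehalose, sucrose, hexose transport and stress. Some names that the rule gives were left out for length. Levels of GAL1 and GAL10 at concentrations outside the test were chosen after their values were seen.

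The fit was tested on simulated data with 2 arrays per group and 50 changed probe sets at each size. For LS at 40% against 5%, 2, 8, 38 and 92% of changes of 1, 2, 4 and 6 on the log2 scale were called, and for HS 0, 10, 48 and 84%. Of 5270 unchanged probe sets 5 and 4 were called. In a simulated shift of 1.5 in 28 genes of the proteasome list, for HS at 50% against 5%, that list was called (camera adjusted p = 3.46e-13) and 0 of the 32 others. The simulated noise was independent, with 1 spread per probe set on all arrays. It held no arrays of wider spread and no correlation between genes or replicates, so these rates need not hold for the real arrays.

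Alternatives set before the data were examined were quantile normalization, median centring of each array, an offset of 0.0564 (the 5th percentile) before the log, a variance trend with robust moderation, a replicate block, only the compared groups in the fit, a required fold of at least 2, S. pombe probe sets included, and each array left out in turn. After seeing the data, 3 more were added: leaving out the 6 LS arrays with an S. pombe median above 1, fitting each yeast alone, and fitting each replicate number alone. Plots were drawn with matplotlib 3.10.9.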

Results

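Transcript levels were measured in 2 baker's yeasts (Saccharomyces cerevisiae), which the labels call only LS and HS, after 60 min of fermentation in a medium that held 0, 5, 10, 20, 30, 40 or 50% sucrose. Each of the 14 combinations of yeast and sucrose concentration had 2 replicate arrays, 28 arrays in all. The number of arrays limits the precision of every value. Poly(A) RNA was hybridised to an Affymetrix array that carries probe sets of S. cerevisiae and of the fission yeast Schizosaccharomyces pombe. The deposited value of a probe set is a ratio to its own usual level across the arrays, so levels can be compared between arrays but not between genes. Values are log2 differences between groups ± SE from limma, with n = 2 arrays per group unless stated. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays.

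The S. pombe probe sets serve as a background, since the samples are S. cerevisiae. Their median ratio was between 0.119 and 0.994 on 22 arrays and between 1.51 and 13.7 on the other 6, which were the second replicates of LS at 0, 5, 10, 20, 30 and 50% sucrose. Across genes, these 6 arrays correlated with their first replicates at r = -0.222 to 0.501, against 0.870 for the LS pair at 40% and 0.471 to 0.725 for the 7 HS pairs. The interquartile range of log2 ratios over S. cerevisiae probe sets was 2.09 to 2.62 on the 6 arrays and 0.729 to 1.57 on HS arrays. All 28 arrays were used as designed, and the counts without the 6 arrays, a choice made after seeing the data, stand beside each comparison.

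**Figure D1:**
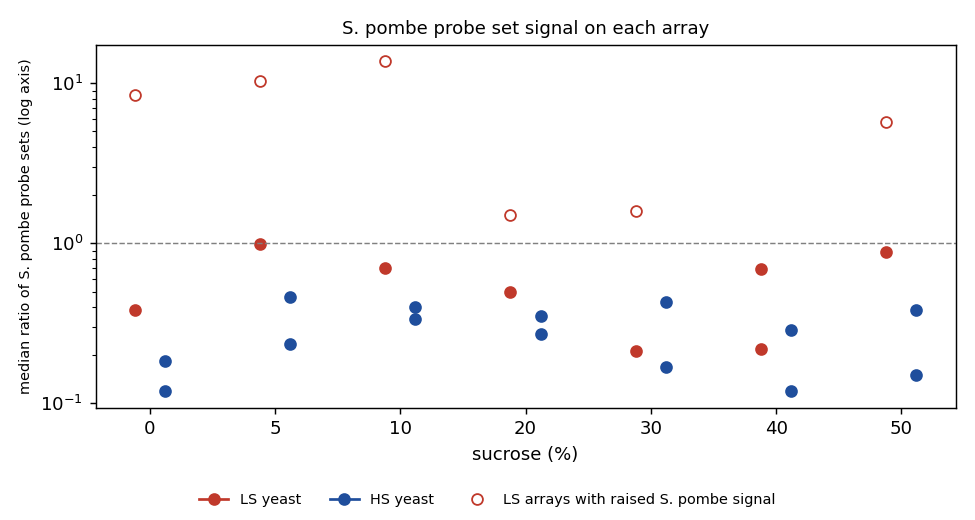
Median ratio of the 1746 S. pombe probe sets on each of the 28 arrays (log axis) against the sucrose concentration in percent; each point is an array, red for LS and blue for HS, and the dashed line marks a ratio of 1. The 6 open points, all LS second replicates, lie at 1.51 to 13.7, and the filled points lie at 0.119 to 0.994.

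The first comparison asked how each yeast responded to the lowest sugar concentration, 5% sucrose, against no sucrose. In HS the enzymes of gluconeogenesis and of fatty acid breakdown fell together. Of the 14 measured genes of gluconeogenesis and the glyoxylate cycle, 8 fell and none rose (12 fell adjusted over the list alone), with a median log2 change of -4.02. FBP1, the fructose-1,6-bisphosphatase of gluconeogenesis, changed by -5.62 ± 1.10 (adjusted p = 0.0075), IDP2 by -5.17 ± 1.05 and the acetyl-CoA synthetase gene ACS1 by -4.67 ± 1.05. Of 13 genes of peroxisomal fatty acid oxidation, 6 fell (9 adjusted over the list alone), among them FOX2 at -6.64 ± 1.03 (adjusted p = 0.002), POT1 at -6.40 ± 1.06 and the transporter subunit PXA1 at -7.31 ± 1.52. Both lists passed the camera test (adjusted p = 2.3e-13 and 1.4e-10), also with an estimated correlation (adjusted p = 0.041 for each, or 0.27 for each without the 6 arrays).

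Stress and storage genes of HS were also lower at 5% than at 0% sucrose. Of 18 targets of the HOG osmotic stress pathway, 6 fell (11 adjusted over the list alone), led by GRE1 at -6.34 ± 1.03 and RTN2 at -6.26 ± 1.48. That list passed camera with the preset and with the estimated correlation (adjusted p = 2e-10 and 0.03), the latter lost without the 6 arrays (adjusted p = 0.27). STL1, a glycerol importer, changed by -4.78 ± 0.86 (27.5-fold, adjusted p = 0.005), and GPD1, which makes the glycerol precursor, by -3.76 ± 0.88 (13.5-fold, adjusted p = 0.02). Trehalose metabolism had 5 of 9 genes lower (6 adjusted over the list alone), including the trehalose-6-phosphate synthase gene TPS1 at -3.68 ± 0.82. Glycogen metabolism had 3 of 10 lower (6 adjusted over the list alone), including the branching enzyme gene GLC3 at -4.78 ± 0.98. These storage lists passed camera with the preset correlation (adjusted p = 4.8e-07 and 2.1e-08) and not with the estimated correlation (adjusted p = 0.1 and 0.085). The antioxidant genes PRX1 and SOD2 fell by 5.95 ± 1.09 and 4.64 ± 1.09, in a list where 4 of 21 genes fell (6 adjusted over the list alone, with 1 higher) and where the camera adjusted p was 0.0024, or 0.35 with an estimated correlation.

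Genes that rose in HS at 5% included HXT1, the low-affinity glucose transporter, at 3.65 ± 0.83 (12.5-fold, adjusted p = 0.017). The largest rises were those of DIP5, an amino acid permease (7.77 ± 1.0, 218-fold, adjusted p = 0.00041), the B-type cyclin gene CLB6 (7.19 ± 1.05), the peptide transporter gene OPT2 (7.10 ± 1.70), the cell wall gene UTR2 (7.02 ± 1.43) and CSI2 (6.75 ± 0.89). The largest falls were those of the transcription factor gene USV1 (-8.61 ± 0.89, 391-fold, adjusted p = 4.3e-05), LEE1 (-7.44 ± 1.92), MTH1, a repressor of hexose transporter genes (-7.34 ± 0.81), PXA1 and NQM1 (-7.09 ± 1.12). The cell wall genes DAN1 and CIS3 rose by 5.28 ± 1.03 and 3.59 ± 0.72, in a list with 2 of 25 higher and 1 lower (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.002, or 0.38 with an estimated correlation). The 127 cytosolic ribosomal protein genes had a median change of 1.04, with none called (0 adjusted over the list alone) and a camera adjusted p of 3e-06, or 0.54 with an estimated correlation. In this comparison the S. pombe probe sets changed by a median of 1.13 and all S. cerevisiae probe sets by 0.307. The median rise of the ribosomal protein genes was thus no larger than that of the background.

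In all, 234 of 5498 probe sets passed in HS, 76 higher and 158 lower at 5%. All 234 were called again without the 6 LS arrays, which enter only through the shared spread, and the count was then 1416, 807 higher and 609 lower. The count fell when any of the 4 compared arrays was left out, to 15 without the first and 53 without the second 0% replicate, and to 37 without the first and 15 without the second 5% replicate.

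In LS the same step from 0 to 5% sucrose gave no probe set past the threshold in the limma fit, against 391 at an unadjusted p under 0.05. HXT1 lay 4.62 ± 0.83 higher at 5% (24.5-fold) with an adjusted p of 0.0502, and 6.27 higher without the 6 arrays. The genes of sucrose and maltose use had a median change of -2.60, with 0 of 9 called over all genes and 7 lower adjusted over the list alone. That list passed camera with the preset and the estimated correlation (adjusted p = 7.9e-09 and 0.018), as did the low-affinity hexose transporters HXT1 and HXT3 in the other direction (median 3.37, adjusted p = 0.00018 and 0.018, 0 of 2 called, 2 adjusted over the list alone). With an estimated correlation both were lost without the 6 arrays (adjusted p = 0.071 and 0.17). SUC2, the invertase gene, had a ratio of 25.4 and 6.77 on the LS arrays at 0% and of 1.68 and 2.97 at 5% (log2 change -2.56 ± 0.97, adjusted p = 0.67). The gluconeogenesis and glyoxylate list had a median of 0.03 in LS, or -0.03 after median centring, with 0 of 14 called (0 adjusted over the list alone, camera adjusted p = 0.75). Its median was -0.51 without the 6 arrays, where camera called it lower (adjusted p = 0.034, or 0.59 with an estimated correlation). In all, 17 lists passed with the preset correlation in LS. Beside the sugar use and HXT lists, their adjusted p was 0.48 to 0.71 with an estimated correlation. Without the 6 arrays, which leaves 1 LS array at each of these concentrations, 8 probe sets passed, 1 higher and 7 lower. Leaving out a single array gave 195 calls without the first and 2 without the second 0% replicate, and 114 without the first and 1 without the second 5% replicate.

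The difference between the yeasts in this step was tested as an interaction. No probe set passed in limma, against 338 at an unadjusted p under 0.05. The gluconeogenesis list had a median HS minus LS difference of -4.22 (0 of 14 called, 9 lower adjusted over the list alone) and the fatty acid oxidation list of -3.72 (0 of 13 called, 5 lower adjusted over the list alone). Their camera adjusted p values were 5.3e-13 and 2e-09, and 0.068 for each with an estimated correlation. The osmotic stress list had a median difference of -2.36 (0 of 18 called, 4 lower adjusted over the list alone, camera adjusted p = 1.1e-05, or 0.097 with an estimated correlation). STL1 differed by -5.92 ± 1.22 between the yeasts, with an adjusted p of 0.17. The fit without the 6 arrays gave 2 calls. Leaving out the first LS replicate at 0% or at 5% gave 8 and 106 calls.

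**Figure D2:**
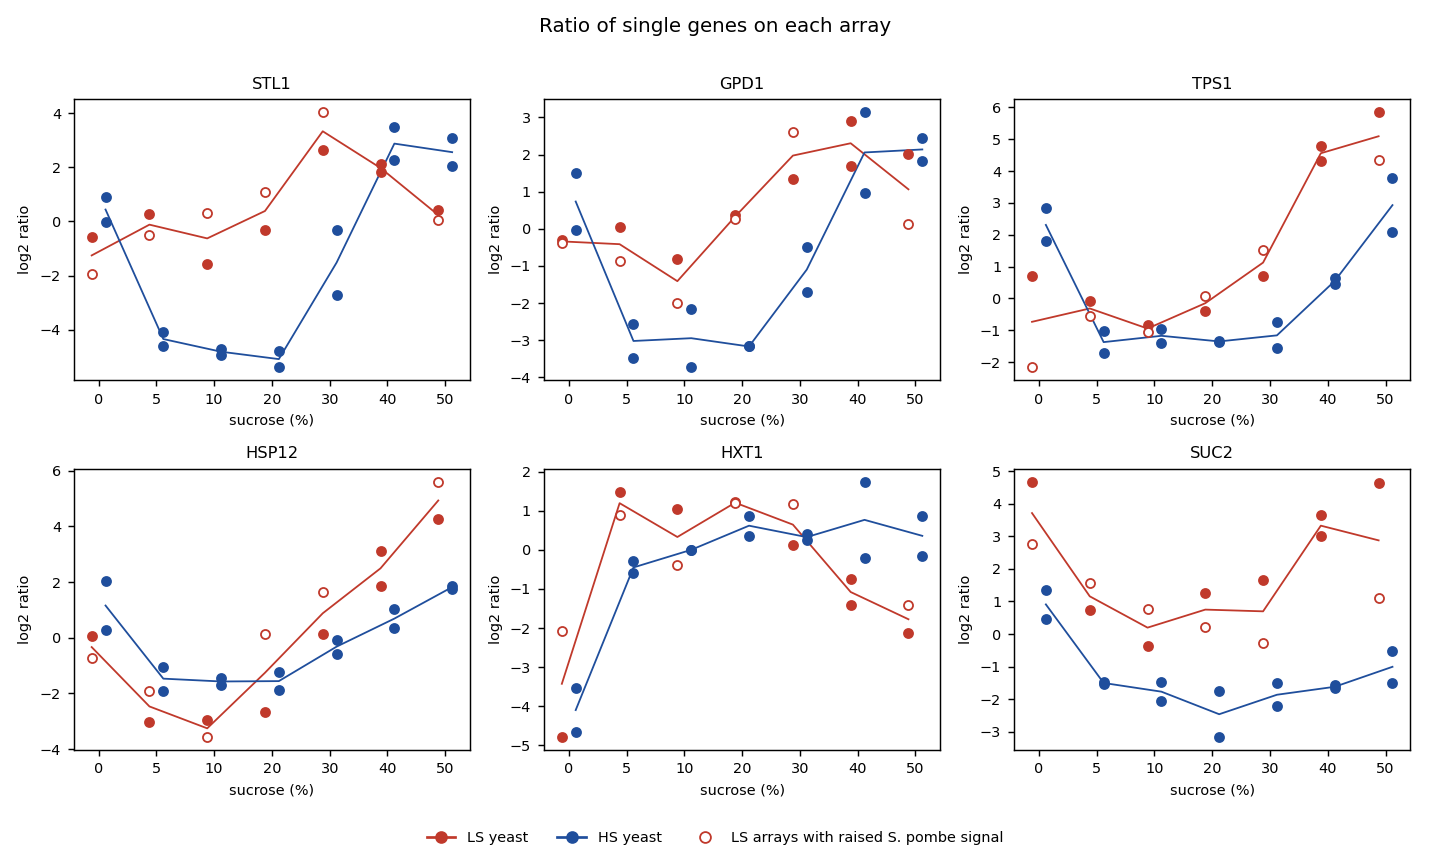
Log2 ratio of STL1, GPD1, TPS1, HSP12, HXT1 and SUC2 on each array against the sucrose concentration in percent, with LS in red and HS in blue; points are arrays, open for the 6 LS arrays with raised S. pombe signal, and lines join the means of 2 replicates. STL1 in HS had ratios of 0.0594 and 0.0408 at 5% and of 11.3 and 4.78 at 40%, and SUC2 in LS lay above SUC2 in HS in the mean at all 7 concentrations.

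High sugar was examined next, as 40% against 5% sucrose. In LS genes of respiration and of the use of non-fermentable carbon rose. Of 14 gluconeogenesis and glyoxylate genes, 7 rose (11 adjusted over the list alone), led by the malate synthase gene MLS1 at 7.68 ± 1.09 (adjusted p = 0.00054) and the phosphoenolpyruvate carboxykinase gene PCK1 at 4.91 ± 0.94. In the tricarboxylic acid cycle 6 of 14 genes rose (10 adjusted over the list alone), among them SDH2 at 5.89 ± 1.15 and IDH2 at 5.34 ± 1.09. In the respiratory chain and ATP synthase 4 of 31 rose (10 adjusted over the list alone), led by the NADH dehydrogenase gene NDI1 at 4.44 ± 1.08. FOX2, PXA1, ECI1 and CTA1 rose among 13 genes of fatty acid oxidation (8 adjusted over the list alone), FOX2 by 6.41 ± 1.03. These 4 lists passed camera with the preset correlation (adjusted p between 2.2e-07 and 2.3e-05) and had adjusted p of 0.17 to 0.31 with an estimated correlation.

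Storage carbohydrate and stress genes rose with them in LS. TPS1 changed by 4.88 ± 0.82 (29.4-fold, adjusted p = 0.0014), from ratios of 0.939 and 0.686 at 5% to 27.7 and 20.0 at 40%. TSL1 and the trehalase gene NTH1 also rose, 6 of 9 trehalose genes in all (8 adjusted over the list alone). Of 10 glycogen genes 5 rose (7 adjusted over the list alone), led by GLC3 at 6.46 ± 0.98 and the synthase gene GSY2 at 5.13 ± 0.99. HSP12, a small membrane-stabilising stress protein gene, rose by 4.96 ± 0.87 (31.2-fold) and the catalase gene CTT1 by 5.64 ± 1.13, as 8 of 18 HOG targets did (11 adjusted over the list alone). Camera adjusted p was 3.3e-06, 2.1e-05 and 2.3e-07 for these lists, and 0.17, 0.17 and 0.12 with an estimated correlation. The glycerol genes STL1 and GPD1 had changes of 2.09 ± 0.86 and 2.72 ± 0.88 (adjusted p = 0.13 and 0.052), and GCY1 and DAK1 rose, 2 of 11 in their list (8 adjusted over the list alone, camera adjusted p = 0.00041, or 0.17 with an estimated correlation). Sugar transport and use genes rose in part: MAL11, the maltose permease gene, by 4.89 ± 1.06, GAL2 by 4.29 ± 1.15 and HXT5 by 3.62 ± 0.75. Of the 9 sucrose and maltose genes 4 rose (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0021, or 0.17 with an estimated correlation).

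Genes of fatty acid elongation, iron uptake, the cell wall and lysine and histidine synthesis were among those that fell in LS at 40%. The largest falls were those of PCL1, a G1 cyclin gene (-6.66 ± 1.25, 101-fold, adjusted p = 0.0025), SWI4, a regulator of G1 transcription (-6.51 ± 1.40), TOS6 (-6.00 ± 1.05), DAN1 (-6.00 ± 1.03) and the ferric reductase gene FRE4 (-5.77 ± 1.01). The fatty acid elongases ELO1, ELO2 and ELO3 fell by 3.16 ± 0.87, 4.04 ± 0.72 and 3.89 ± 0.63, which were 3 of 8 fatty acid genes (3 adjusted over the list alone, camera adjusted p = 0.043, or 0.46 with an estimated correlation). Iron uptake had 4 of 18 genes lower (5 adjusted over the list alone), with ENB1 at -4.47 ± 0.72. Cell wall proteins had 7 of 25 lower (13 lower and 1 higher adjusted over the list alone), with TIR1 at -3.61 ± 0.82. Lysine and histidine biosynthesis had 4 of 15 lower (7 adjusted over the list alone), with LYS2 at -2.74 ± 0.72. Camera adjusted p was 0.0013, 0.00045 and 4.2e-05 for these lists, and 0.17, 0.31 and 0.2 with an estimated correlation. The ribosomal protein genes had a median of -1.85 with 6 of 127 lower (0 adjusted over the list alone, camera adjusted p = 5.5e-13, or 0.4 with an estimated correlation).

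In LS 595 probe sets passed between 40% and 5% sucrose, 357 higher and 238 lower. The largest rises were AMS1, a vacuolar mannosidase gene (8.40 ± 1.24, 337-fold), PXA1 (8.16 ± 1.52), YHR138C (7.97 ± 1.13), STF2 (7.77 ± 1.05) and the protease inhibitor gene PAI3 (7.68 ± 1.65). Without the 6 arrays 2158 passed (865 higher, 1293 lower), 573 of the 595 among them in the same direction, and with only the 4 compared arrays in the fit none passed. The count was 171 and 143 without the first and the second 40% replicate. The S. pombe probe sets changed by a median of -3.10 in this comparison, and by -1.43 without the 6 arrays, which include the second 5% replicate.

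In HS the step from 5 to 40% sucrose gave fewer calls in the fit of all arrays, with glycerol genes among the rises. STL1 rose by 7.22 ± 0.86 (149-fold, adjusted p = 2e-04) and GPD1 by 5.08 ± 0.88 (33.8-fold, adjusted p = 0.0046), 2 of 11 genes of glycerol metabolism (2 adjusted over the list alone, camera adjusted p = 0.00022, or 0.3 with an estimated correlation). The methylglyoxal reductase gene GRE2 rose by 5.13 ± 0.80, the call among 18 HOG targets (1 adjusted over the list alone), whose median was 1.70 with a camera adjusted p of 9.5e-05, or 0.3 with an estimated correlation. UBP11 (7.33 ± 1.52, with 1 array at the lowest value of the table), the DNA damage responsive gene DDR48 (5.89 ± 1.25), ANS1 (5.19 ± 1.16) and PHM8 (5.16 ± 1.07) were the other largest rises. TPS1 and HSP12 had changes of 1.92 ± 0.82 and 2.16 ± 0.87 (adjusted p = 0.42 and 0.37), and SUC2 of -0.12 ± 0.97. TPS1, HSP12 and further HOG targets passed as higher without the 6 LS arrays, which enter here only through the shared spread.

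The largest falls in HS were those of CLN2, CSI2, PCL1, TOS6 and YOX1. The G1 cyclin genes CLN2 and PCL1 changed by -8.42 ± 1.21 (342-fold, adjusted p = 0.0015) and -7.61 ± 1.25, CSI2 by -8.33 ± 0.89 (adjusted p = 6.9e-05), TOS6 by -6.91 ± 1.05 and the homeobox repressor gene YOX1 by -6.41 ± 0.90. The cell wall genes TIR1, DAN1 and CRH1 fell by 5.17 ± 0.82, 4.65 ± 1.03 and 3.29 ± 0.73, which were 3 of 25 in their list (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.1e-06, or 0.41 with an estimated correlation). Ergosterol biosynthesis had a median of -1.21 with 0 of 23 called (0 adjusted over the list alone, camera adjusted p = 9e-05, or 0.71 with an estimated correlation), and 14 of the 23 were lower without the 6 arrays.

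In HS 64 probe sets passed, 19 higher and 45 lower. The S. pombe probe sets changed by a median of -0.899 in this comparison. That HS had fewer calls than LS depended on the fit. With each yeast fitted alone 760 passed in HS and 52 in LS, and with only the compared groups 302 and 0. After quantile normalization 461 passed with 226 higher and 235 lower, and without the 6 arrays 865 passed (341 higher, 524 lower), all 64 among them. The count was 2 and 10 without the first and the second 5% replicate, and 10 and 22 without the first and the second 40% replicate.

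The interaction asked whether the yeasts differed in the response to 40% sucrose. FRE4 fell in LS and had a change of 2.47 ± 1.01 in HS (adjusted p = 0.39), a difference of 8.24 ± 1.43 (adjusted p = 0.03). The galactokinase gene GAL1 and the epimerase gene GAL10 differed by -6.80 ± 1.18 and -6.64 ± 1.17, and the oxoprolinase gene OXP1 by -5.24 ± 0.96 (adjusted p = 0.03, 0.03 and 0.036). GAL1 had ratios of 71.2 and 65.4 in LS and of 0.377 and 0.393 in HS at 40%, against 2.60 and 0.436 in LS and 0.618 and 0.728 in HS at 5%. STL1 differed by 5.12 ± 1.22 with an adjusted p of 0.19, or 0.017 without the 6 arrays. The tricarboxylic acid cycle list differed by a median of -2.77 (0 of 14 called, 6 lower adjusted over the list alone), the respiratory chain list by -2.25 (0 of 31, 0 adjusted over the list alone) and ribosomal proteins by 1.67 (0 of 127, 0 adjusted over the list alone). Their camera adjusted p was 2.8e-09, 1.6e-08 and 3e-14, and 0.31, 0.31 and 0.43 with an estimated correlation. The S. pombe probe sets differed by a median of 2.16 in this interaction, or 0.528 without the 6 arrays.

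These 4 genes were all the calls of the interaction, 1 higher and 3 lower, against 447 probe sets at an unadjusted p under 0.05. Quantile normalization gave 5, 4 of them higher and 1 lower, the fit without the 6 arrays gave 437 (211 higher, 226 lower, with these 4 among them), and the fit on the compared groups alone gave none. Leaving out the first LS replicate at 5% gave 24 calls, and leaving out the second HS replicate at 40% gave 6. None passed without any other single array of the 4 groups.

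**Figure D3:**
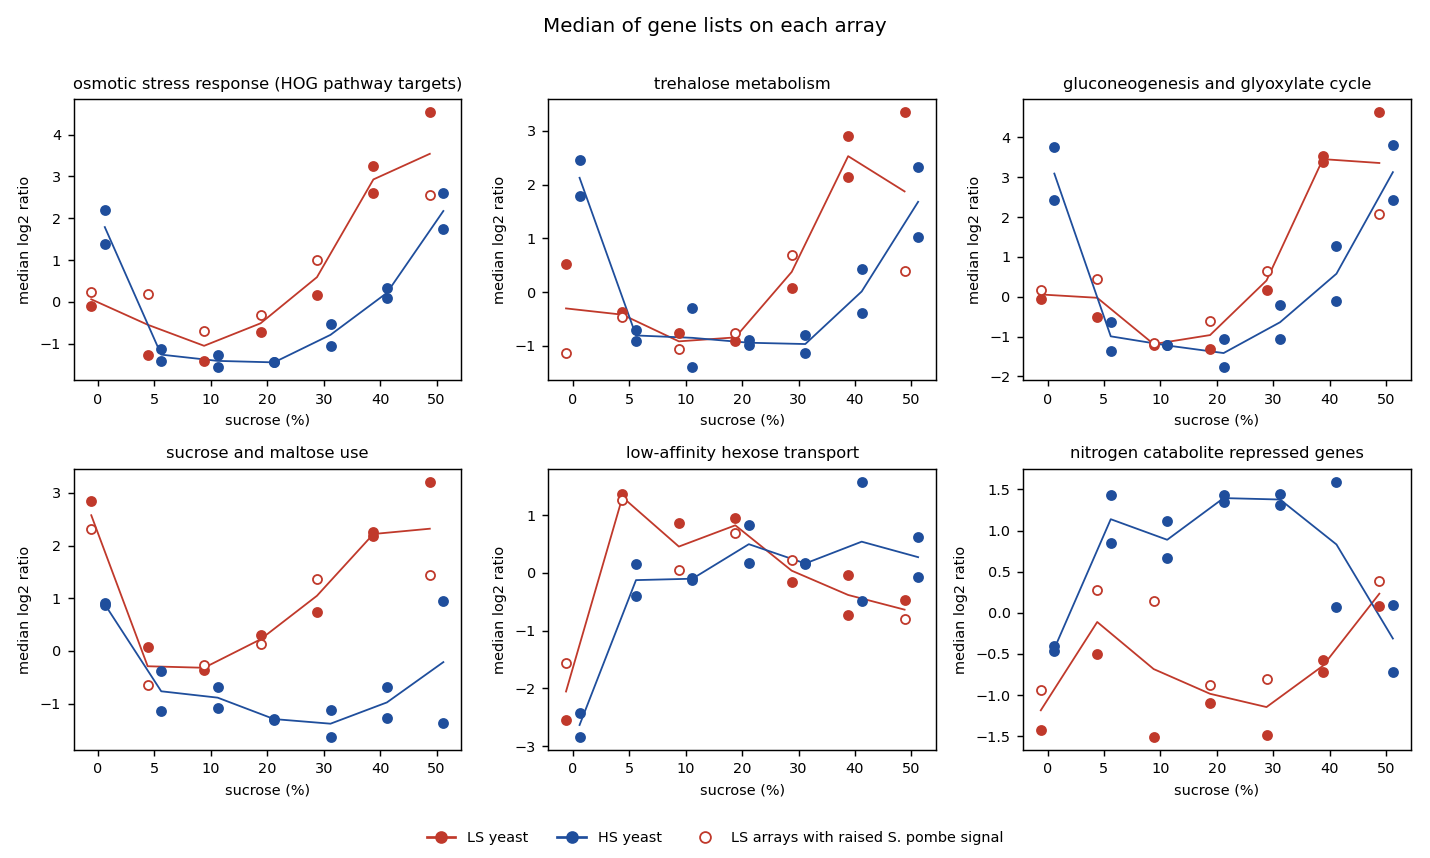
Median log2 ratio of 6 gene lists on each array against the sucrose concentration in percent, with LS in red and HS in blue; points are arrays, open for the 6 LS arrays with raised S. pombe signal, and lines join the means of 2 replicates. The gluconeogenesis and glyoxylate list was high in HS at 0% and 50% sucrose and in LS at 40% and 50%, with a median change of -4.02 from 0 to 5% in HS and of 3.55 from 5 to 40% in LS.

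At 50% sucrose against 5%, genes of gluconeogenesis, fatty acid oxidation, trehalose metabolism and osmotic stress rose in HS. Of 14 gluconeogenesis and glyoxylate genes 10 rose (11 adjusted over the list alone), with FBP1 at 5.59 ± 1.10 and MLS1 at 4.86 ± 1.09. Fatty acid oxidation had 7 of 13 higher (9 adjusted over the list alone), with FOX2 at 7.48 ± 1.03 (adjusted p = 0.00056) and the acyl-CoA oxidase gene POX1 at 7.73 ± 1.67. TPS1 rose by 4.30 ± 0.82 (19.7-fold), in a list with 4 of 9 trehalose genes higher (6 adjusted over the list alone), and HSP12 by 3.29 ± 0.87, among 9 of 18 HOG targets (11 adjusted over the list alone). STL1 and GPD1 rose by 6.90 ± 0.86 and 5.16 ± 0.88, with GCY1 3 of 11 glycerol genes (6 adjusted over the list alone). Camera adjusted p for these 5 lists was between 3e-10 and 0.001, and 0.065 to 0.31 with an estimated correlation. The largest rise was that of USV1 (10.63 ± 0.89, 1580-fold, adjusted p = 1.3e-06), followed by UBP11, LEE1, PXA1 and POX1.

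Some genes of ergosterol synthesis, fatty acid elongation, the cell wall and lysine and histidine synthesis fell in HS at 50%. The sterol desaturase gene ERG3 changed by -3.85 ± 0.68 and ERG24 by -3.39 ± 0.87, 4 of 23 ergosterol genes being lower (8 adjusted over the list alone). ELO2 and ELO1 changed by -4.38 ± 0.72 and -4.07 ± 0.87, among 3 of 8 fatty acid genes lower (3 adjusted over the list alone, camera adjusted p = 0.018, or 0.5 with an estimated correlation). SCW10 and TIR1 changed by -5.82 ± 1.19 and -5.54 ± 0.82, with 5 cell wall genes of 25 lower and 1 higher (14 lower and 1 higher adjusted over the list alone). LYS9, LYS2, LYS1 and HIS7 fell by 3.27 to 3.69, among 5 of 15 lysine and histidine genes (6 adjusted over the list alone). Camera adjusted p was 1.8e-05 for ergosterol, 7e-06 for the cell wall and 2.6e-06 for lysine and histidine, and 0.43, 0.24 and 0.18 with an estimated correlation. The largest falls were those of OPT2 (-8.13 ± 1.70, 281-fold), CLN2 (-7.78 ± 1.21), TOS6 (-7.35 ± 1.05), PCL1 (-6.63 ± 1.25) and SRL1 (-6.50 ± 1.27). In all 414 probe sets passed in HS, 226 higher and 188 lower. In the fit without the 6 arrays 2162 passed (967 higher, 1195 lower), all 414 among them, and quantile normalization gave 470 higher and 487 lower. The count was 98 and 62 without the first and the second 5% replicate, and 255 and 73 without the first and the second 50% replicate.

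In LS at 50% the stress and storage genes rose as well. HSP12 changed by 7.40 ± 0.87 (169-fold, adjusted p = 5.6e-05), SIP18 by 8.40 ± 1.5 and PAI3 by 9.65 ± 1.65 (803-fold), with 11 of 18 HOG targets higher (11 adjusted over the list alone). TPS1 rose by 5.41 ± 0.82 (42.5-fold), MLS1 by 7.88 ± 1.09 and GLC3 by 7.02 ± 0.98, where 4 of 9 trehalose (6 adjusted over the list alone), 6 of 14 gluconeogenesis (11 adjusted over the list alone) and 6 of 10 glycogen genes (7 adjusted over the list alone) were higher. YHR138C (9.53 ± 1.13), EGO4 (9.16 ± 1.14), the protease inhibitor gene PBI2 (9.06 ± 1.30) and TMA10 (8.48 ± 1.20) were the other largest rises. Camera adjusted p for these 4 lists was between 3.9e-08 and 6.4e-05, and 0.066 to 0.3 with an estimated correlation. STL1 and GPD1 had changes of 0.35 ± 0.86 and 1.48 ± 0.88 (adjusted p = 0.83 and 0.28), and HXT1 fell by 2.97 ± 0.83.

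Ribosome biogenesis had 7 of 47 genes lower in LS at 50% (9 adjusted over the list alone), with RRP12 at -4.71 ± 1.48 and NOG1 at -3.08 ± 0.69 (list camera adjusted p = 3.2e-06, or 0.51 with an estimated correlation). The permease genes ALP1 (-5.79 ± 1.11), BIO5 (-5.77 ± 1.02) and GNP1 (-5.49 ± 1.33, with 1 array at the lowest value of the table) were among the largest falls, with YMR230W-A and MRX11. In LS 739 probe sets passed, 429 higher and 310 lower, against 2128 without the 6 arrays (973 higher, 1155 lower) with 649 of the 739 among them. Quantile normalization left 105, 79 higher and 26 lower, and the fit on the compared groups alone left 34.

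Intermediate concentrations gave few calls against 5%. The simulation for 40% against 5%, with independent noise, called 8 and 10% of log2 changes of 2 in LS and HS. In LS 0, 0 and 14 probe sets passed at 10, 20 and 30% sucrose, and in HS 0, 0 and 1, with 232, 529 and 776 in LS and 6, 12 and 126 in HS at an unadjusted p under 0.05 in limma. Without the 6 arrays the counts were 0, 1 and 257 in LS and 0, 0 and 36 in HS.

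The comparison of the yeasts at matched sucrose asked which genes differed in the mean over the 7 concentrations. Sugar use genes were lower in HS. SUC2 differed by -3.15 ± 0.37 (8.85-fold, adjusted p = 1.4e-05), MAL11 by -3.05 ± 0.40 and the isomaltase gene IMA5 by -3.96 ± 0.48, with 5 of 9 sucrose and maltose genes lower (6 adjusted over the list alone). GAL2 differed by -4.75 ± 0.43 and HXT7 by -1.77 ± 0.34, 4 of 5 high-affinity hexose transporters being lower (4 adjusted over the list alone). QCR8 and CYT1 of the respiratory chain differed by -5.08 ± 0.42 and -2.51 ± 0.39, among 7 of 31 lower (7 adjusted over the list alone). The dihydroxyacetone kinase gene DAK2 (-5.85 ± 0.66, a probe set of low signal), STL1 (-1.97 ± 0.33) and GPD1 (-1.26 ± 0.33) were among 5 of 11 glycerol genes lower (5 adjusted over the list alone), and TPS1 differed by -1.13 ± 0.31. These means hide opposite signs: HS minus LS was 1.69, 0.90 and 2.32 for STL1 at 0, 40 and 50%, 1.07 and 1.07 for GPD1 at 0 and 50%, and 3.04 for TPS1 at 0% (none called), and HXT7 lay above LS at 10%. Camera adjusted p for the 4 lists was 4e-05, 0.00046, 0.017 and 0.017, and 0.11, 0.45, 0.7 and 0.59 with an estimated correlation.

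Genes of nitrogen use were higher in HS. Of 24 genes under nitrogen catabolite repression 13 were higher and none lower (16 adjusted over the list alone), with the allantoin pathway genes DAL2 at 2.98 ± 0.37, DAL3 at 2.76 ± 0.31 and DAL1 at 2.57 ± 0.31 and the transaminase gene UGA1 at 2.35 ± 0.40; DAL2 lay below LS at 50%. The list's camera adjusted p was 1.4e-09, or 0.091 with an estimated correlation. The flavohemoglobin gene YHB1 (3.57 ± 0.42, 11.9-fold), YIL014C-A (4.11 ± 0.86) and FRM2 (2.44 ± 0.47) were also among the largest positive differences. The largest negative ones were REE1 (-6.18 ± 0.66, 72.5-fold), YOL159C-A (-6.11 ± 0.51), YIR042C (-5.96 ± 0.64), DAK2 and COS7 (-5.73 ± 0.45), each lower in HS at all 7 concentrations. COS7 is read by a probe set shared with related genes. REE1, YOL159C-A, DAK2 and COS7 each lay in a run of neighbouring genes called lower in HS, and IMA5 lay in that of REE1. FLO11, which codes for a cell surface adhesin, differed by -3.28 ± 0.41.

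Over all concentrations 848 probe sets differed, 223 higher and 625 lower in HS (n = 14 arrays per yeast, taken as independent). Quantile normalization gave 1227, with 646 higher and 581 lower, and 1589 passed without the 6 arrays, which kept 568 of the 848 (67.0%). The ribosomal protein list, with 20 of 127 lower (47 adjusted over the list alone, camera adjusted p = 8.4e-09, or 0.7 with an estimated correlation), had none lower without the 6 arrays (camera adjusted p = 0.095). The replicate 1 arrays alone gave 315 and the replicate 2 arrays alone 1338. Leaving out an array moved the count past 1.5 times at 6 arrays: to 1428 and 1449 without the first LS replicates at 0 and 10%, 536 without the second LS replicate at 30%, 500 and 538 without the second HS replicates at 5 and 10%, and 545 without the first HS replicate at 50%. The S. pombe probe sets differed by a median of -2.41, or -1.03 without the 6 arrays. When they were included in the fit of all arrays, 1201 of the 1746 were called lower in HS and 0 higher. At single concentrations 45, 0, 1, 12, 8, 213 and 53 probe sets differed at 0, 5, 10, 20, 30, 40 and 50% sucrose, with 442 at an unadjusted p under 0.05 for 5%. These counts were, without the 6 arrays, 650, 32, 26, 95, 72, 1632 and 955.

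The responses of the yeasts were set side by side across genes, which are not independent replicates. The log2 changes from 5 to 40% sucrose correlated at Pearson r = 0.508 and Spearman rho = 0.473 between LS and HS. All 36 probe sets called in both moved the same way, where independent lists would share 3.18 in the same direction. From 0 to 5% the correlation was r = 0.328 and rho = 0.335, or 0.534 and 0.551 without the 6 arrays. From 5 to 50% it was r = 0.638 and rho = 0.576. Of 223 shared calls 221 were in the same direction, where independent lists would share 28.2 in the same direction. No array is shared between the yeasts. Both sets of calls used the same spread of each probe set, however, so the lists are not independent and these baselines may be too low.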

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

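The tests of the S. pombe ribosomal protein probe sets, of other splits of the arrays and of neighbouring genes were set before their results were seen; the other tests in this part were chosen after. The S. pombe probe sets, which no comparison used, gave a signal on 6 arrays above that on the other 22. The second LS replicates had median ratios of 8.44 at 0%, 10.3 at 5%, 13.7 at 10%, 1.51 at 20%, 1.59 at 30% and 5.72 at 50% sucrose, against at most 0.994 elsewhere.

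For these 6 arrays, S. pombe RNA in the samples was weighed first. Its abundant ribosomal protein transcripts were predicted to rise above other S. pombe probe sets. The 14 ribosomal protein probe sets rose less in 5 of the 6 pairs of replicates, and the largest difference was 0.274 (log2). Ratios carry no level, and signal of S. cerevisiae RNA at these probe sets was not measured. The test therefore does not exclude S. pombe RNA. A property of the LS yeast was predicted to raise the first LS replicates as well. Each of the 6 arrays had an S. pombe median at least 1.59 (log2) above that of its own partner. As the 6 arrays were picked by this median, that they lay above their partners was fixed beforehand. The S. pombe probe sets still differed by a median of -1.03 (HS minus LS) without the 6 arrays. A part played by the yeast is therefore not excluded. Low signal over background may account for part of the pattern, as the 125 S. cerevisiae probe sets of low signal rose more than the others from the first to the second replicate in all 6 pairs, by at least 1.44 (log2). It leaves open the rise of the abundant ribosomal protein transcripts of S. cerevisiae, which at 20 and 30% rose by 2.70 and 3.25 (log2), against 1.77 and 3.06 for the probe sets of low signal. No biological explanation was tested beyond the yeast, and the labels give no batch.

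The step from 0 to 5% sucrose differed between the yeasts in the gluconeogenesis list, which fell in HS with a median of -4.02 and had a median of 0.03 in LS, or -0.03 after median centring and -0.51 without the 6 arrays (camera adjusted p = 0.034, lower, or 0.59 with an estimated correlation). If the wide spread of the 6 arrays had hidden a fall in LS as large as that in HS, the difference would have come near 0 without them; it was -3.69 against -4.22 with all arrays, with 13 of 14 genes below 0 in both fits. The median log2 ratio of HXT1 and HXT3 was -2.55 and -1.55 on the first and second LS array at 0%. The higher value lay 0.75 below the lowest other LS array (a difference of -0.754). This argues against a wrong concentration label on the first array. HXT1 by itself had ratios of 0.0363 and 0.239 in LS at 0%, against 0.229 and 0.373 at 50%. It did not set the second array, 1 of the 6, apart from 50%. A wrong label on that array is therefore not excluded. At 0% sucrose the gluconeogenesis list had a median HS minus LS difference of 3.87, or 3.5 without the 6 arrays. The difference between the yeasts thus lay largely in the medium without sucrose. A difference in the level of these genes without sugar, or in how they respond to it, may remain as a hypothesis, found and tested on the same arrays. The camera adjusted p of the list was 0.068 with an estimated correlation. Without the 6 arrays the LS step rests on 1 array at each concentration.

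HS against LS over all concentrations was set beside other splits of the 28 arrays into 14 and 14. Of 100 splits, 1 called as many probe sets, the real one. It had 883 calls in a model of yeast and concentration, and the highest other split had 1. Every other split mixed the yeasts and took single arrays as exchangeable. The test therefore cannot tell the yeast from any other grouping that follows the same labels, and it does not exclude chance. Setting the 6 arrays against the other 22 called 2794, which points to a structure of the samples; the first replicates alone gave 315 calls for HS against LS, the second alone 1338, and the second against the first replicates 111. The 6 arrays as the whole source are argued against by the 67% of calls that were made in the same direction without them. Different copy number of chromosome segments could place called genes side by side, and 31% of called genes had a neighbour called the same way, 13.3 percentage points above the mean of 1000 random draws (17.7%, highest 23.9%); this lies between the bounds set beforehand, so copy number and regulation of neighbouring genes cannot be told apart. Sequence differences between the yeasts at the probes were not tested and stay open, as does a difference in regulation.

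The interaction test singled out 4 genes whose response to 40% against 5% sucrose differed between the yeasts. After quantile normalization only 1 probe set was called lower, so GAL10, GAL1 and OXP1 did not all keep their call. The HS minus LS difference was -6.64 for GAL10, -6.80 for GAL1, -5.24 for OXP1 and 8.24 for FRE4 (log2, 2 arrays in each of 4 groups). OXP1 had ratios of 10.1 and 13.2 at 40% and of 1.17 and 1.10 at 5% in LS, and of 0.242 and 0.175 at 40% and of 0.743 and 0.782 at 5% in HS. FRE4 had ratios of 0.109 and 0.10 at 40% in LS and of 5.51 and 2.23 in HS. The explanations for these genes were not tested.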

How the results depend on the processing

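The alternatives without the 6 arrays, with 1 yeast alone and with 1 replicate number alone were chosen after seeing the data. No called gene that the text names changed sign under the alternatives run for named genes, while the majority direction of calls and the sign of small or uncalled list medians did change in places, and where a count moved the cause was not tested. Quantile normalization gave 105 calls for LS at 50% against 5%, 623, 461 and 957 for HS at 5% against 0% and at 40% and 50% against 5%, and 2 for the interaction of 5% against 0%. Median centring and the offset each gave 4 for LS at 5% against 0%. The variance trend gave 1 for the interaction of 40% against 5%, and the replicate block 1 for that of 5% against 0%. With S. pombe probe sets included, the counts were 115 for HS at 5% against 0%, 37 for HS at 40%, 2211 for HS against LS (297 higher, 1914 lower) and 0 for the interaction of 40%. Without the 6 arrays they were 8, 2158 and 2128 for the LS steps to 5, 40 and 50%, 1416, 865 and 2162 for the HS steps, 1589 for HS against LS, and 2 and 437 for the interactions at 5 and 40%. The compared groups alone gave 0 and 34 for LS at 40 and 50%, 1142, 302 and 1366 for the HS steps, and 0 for the interaction of 40%, from fewer samples. A single yeast in the fit gave 52 and 55 for LS at 40 and 50% and 1294, 760 and 2101 for the HS steps. HS against LS gave 315 with replicate 1 and 1338 with replicate 2 arrays alone. Leaving out 1 array, where the lone sample is assumed to vary like the other groups, gave 1 to 195 for LS at 5%, 143 to 552 at 40% and 552 to 659 at 50%, 15 to 53, 2 to 22 and 62 to 255 for the HS steps, 500 to 1449 for HS against LS, and 0 to 106 and 0 to 24 for the interactions.

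The other alternatives kept these counts within 1.5 times. Of the named gene results, 341 kept their side of the threshold with quantile normalization, 89 lost and 7 gained a call; without the 6 arrays 400 kept, 20 lost and 17 gained. Over all pairs of a named gene result and an array left out, 932 lost, 9 gained and 2679 kept. Of the list results, 150 lost their call with an estimated correlation and 147 kept their side; without the 6 arrays none passed with an estimated correlation in the 9 main comparisons. The median change over all S. cerevisiae probe sets moved between scalings: 0.31 as deposited, 0.15 with quantile normalization and 0.07 with median centring for HS at 5% against 0%; -0.16, 0.00 and 0.03 for LS at 40%; -0.21, -0.08 and -0.09 for LS at 50%; -0.13, -0.04 and 0.00 for HS at 50%. For HS against LS it was -0.02 as deposited and 0.10 with quantile normalization, and for the interaction of 5% it was 0.16, 0.10 and -0.02. Deviations of replicates from their group mean correlated across genes at a median of 0.39 between LS groups, 0.29 between HS groups and -0.09 between the yeasts. In the labels, replicates of different groups share only a number. The main fit took the arrays as independent, and the replicate block was common to both yeasts. The p-values of HS against LS therefore do not allow for deviations shared within a yeast. A filter on low values was not run, since the ratios carry no level. Raw signal and background were not analysed here, so what they limit was not measured.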

Other observations

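Both tests in this part were chosen after their results were seen. STL1 in HS had ratios of 0.975 and 1.89 at 0%, 0.0594 and 0.0408 at 5%, 0.0239 and 0.0363 at 20%, 0.153 and 0.795 at 30%, 11.3 and 4.78 at 40% and 8.38 and 4.14 at 50%. In LS its ratios were 6.18 and 16.4 at 30%, 4.32 and 3.58 at 40% and 1.35 and 1.03 at 50%. GPD1 had ratios of 2.55 and 6.04 in LS and of 0.305 and 0.714 in HS at 30%. TPS1 in LS had ratios of 1.64 and 2.89 at 30%, 27.7 and 20.0 at 40% and 57.6 and 20.2 at 50%, and in HS of 0.594 and 0.336 at 30%, 1.55 and 1.37 at 40% and 4.26 and 13.6 at 50%. GAL1 and GAL10 in LS were also high at 0% (GAL1 13.7 and 9.45, GAL10 35.7 and 10.1) and at 50% (GAL1 180.3 and 63.6, GAL10 363.3 and 190.9), while in HS GAL1 stayed between 0.257 and 1.03 on all 14 arrays.

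The glycerol genes may respond at a lower sucrose concentration in LS than in HS. The HS minus LS response of STL1 to 30% against 5% was -0.624 ± 1.22 (log2, limma, adjusted p = 1), or 0.479 ± 1.20 without the 6 arrays, so the test does not decide. STL1 in LS already had ratios of 1.22 and 0.698 at 5%, against 0.0594 and 0.0408 in HS. The HS minus LS difference of STL1 was -4.225 ± 0.862 at 5% (limma, adjusted p = 0.13). At 20 and 30% it was -5.47 ± 0.862 and -4.85 ± 0.862 (limma, adjusted p = 0.008 and 0.023). These are differences in level, not in response.

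The HS response at 50% sucrose may be closer to the LS response at 40% than the HS response at 40% is. Over the 357 probe sets that rose in LS at 40% (median 4.06), the median HS change was 1.18 at 40% and 2.81 at 50%, a ratio of 2.38. Without the 6 arrays another, larger set rose in LS, and its median HS changes were 0.918 and 2.08, a ratio of 2.27. Across genes, which are not independent replicates, the LS response at 40% correlated with the HS response at r = 0.508 for 40% and 0.711 for 50%. A stronger response raises such a correlation by itself, and these responses share no array between the yeasts.

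Neighbouring genes that differed the same way between the yeasts formed runs. COS7, MPH2, SOR2, HXT15, THI13 and AAD4 had a median HS minus LS difference of -3.65, and DAL1, DAL4, DAL2, DCG1, DAL7 and DAL3 of 2.39. HXT9, YJL218W, REE1, IMA5 and HXT8 had a median of -3.75. Among the runs found, the DAL run alone was higher in HS. Whether copy number, sequence at the probes or regulation lay behind the runs was not settled.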
